A study of Homo sapiens with 24 samples.

How the data were processed

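RNA of the MCF7/BUS human breast cancer cell line was measured on 24 Affymetrix oligonucleotide arrays in 8 groups of 3. Per the labels, cells were kept for 16 h in phenol red-free medium with 5% charcoal-stripped serum before exposure to a compound or to 0.1% ethanol for 48 h, and 6 µg of RNA per sample was labelled with biotin. The deposited values are MAS5 signal intensity per probe set on a linear scale. Neither the version of MAS5 nor its scaling target is stated, and the table holds no detection calls. The labels call the arrays of each group biological replications and do not say whether these were separate cultures.

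The table held 22283 probe sets, of which 68 were AFFX controls. The remaining 22215 were named through the platform annotation: 19065 carried 1 gene symbol, 1043 carried several and 2107 carried none. The annotation gives no genome build for these probe sets, so no positions are given. The 2% trimmed mean of an array ran from 64.6 to 314, a ratio of 4.86, which was over the limit of 1.2 set for treating the table as scaled alike. Each array was therefore multiplied to a common trimmed mean of 153. Values under 1 were set to 1 and log2 transformed. Probe sets whose mean log2 signal over the 24 arrays was at or above the median of 5.72 were tested, which left 11108 probe sets and 6921 genes. A gene was represented by its probe set with the highest mean log2 signal among those with 1 symbol, and is given by its symbol.

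A linear model with 1 mean per group was fitted to all 24 arrays with limma 3.58.1 in R 4.3.3, with moderated variances that followed the mean signal. It had 16 residual and 8.02 prior degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method within each comparison at 0.05. Each treatment was compared with vehicle and with estradiol, genistein 10 µM with 3 µM, and genistein 3 µM with daidzein. The average of the 7 treatments was compared with vehicle, and a moderated F test covered any difference among the 8 groups. These choices, the gene lists and the rule for named genes were fixed before the data were examined.

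In each comparison with vehicle, the named genes were those past the threshold whose 3 arrays lay on 1 side of the other 3, taking the 10 with the largest rise and the 10 with the largest fall. In other comparisons 5 were taken in each direction. A fixed panel of estrogen, cell cycle and xenobiotic genes was added in every comparison, and members of the fixed lists were named as examples after their values were seen. The 29 fixed lists were tested with camera of limma at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over all lists and comparisons with vehicle (196 tests) and separately over the other comparisons (224 tests). Every list was also tested with a correlation estimated from the data, and 35 of 71 and 28 of 53 calls held. In 19 and 30 tests the sign of the list's median, mean and test differed, and none of these tests passed. The median of the estrogen-induced genes per array was compared by a two-sided exact permutation test. Responses were compared by Pearson correlation and covariance across probe sets, beside values from 100 simulated sets of unchanged groups that shared the vehicle arrays.

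The pipeline was tested on simulated data made from these arrays. For estradiol against vehicle, 13.4% of probe sets with an added log2 change of 0.5, 73.1% with 1 and 100% with 2 were recovered, with 4 of 128 calls on unchanged probe sets. That share was higher than the 5% aimed at in some other comparisons, at 14 of 144 calls for bisphenol A and 11 of 149 for PPT against vehicle. Against estradiol it was highest for daidzein, at 18 of 155. Each comparison was simulated once, from the same means and spreads with independent errors. The shares therefore differ by the random draw and not by the compound.

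The alternatives were quantile normalization, log2 of the signal plus 16, no filter on dim probe sets, a fit on the 6 arrays compared, the replicate number as a block, an estimated inter-gene correlation, and leaving out each replicate. Array brightness as a covariate was added after seeing the data. The number of arrays limits the precision. P-values measure the spread between these arrays only. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.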

Results

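Transcript levels were measured in MCF7/BUS, an estrogen-responsive human breast cancer cell line, after 48 h with a hormone, a plant or industrial compound, or vehicle alone. The groups were vehicle, estradiol at 30 pM, genistein at 3 and 10 µM, daidzein at 1 µM, bisphenol A at 1 nM, nonylphenol at 10 nM and PPT at 3 nM, with 3 arrays in each. Estradiol is the main natural estrogen. Genistein and daidzein are soy isoflavones, bisphenol A is a monomer of polycarbonate plastic, and nonylphenol is a breakdown product of industrial surfactants. PPT is given in the labels by its abbreviation. The comparisons ask which genes each compound changed and how far its response resembled that of estradiol. Log2 changes below are given ± SE from limma with n = 3 arrays per group, and p-values are adjusted by the Benjamini-Hochberg method. The labels call the arrays of a group biological replications but do not say that these were separate cultures. P-values measure only the spread between these samples, part of which may be technical.

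The arrays differed in brightness before scaling. The 2% trimmed mean signal was 112, 91.6 and 64.6 in vehicle, 135, 100.5 and 109 in estradiol, and 79.8, 98.9 and 114 in genistein 3 µM. It was 144, 223 and 192 in genistein 10 µM, 264, 206 and 248 in daidzein, and 195, 202 and 192 in bisphenol A. Nonylphenol arrays had 169, 314 and 274, and PPT arrays had 101, 147 and 222. The mean 3' to 5' signal ratio of ACTB, a sign of RNA integrity, was 0.935 ± 0.062 (SD, n = 3) in vehicle, 0.938 ± 0.053 in estradiol and 0.886 ± 0.049 in genistein 3 µM. It was 1.22 ± 0.25 in genistein 10 µM, 1.15 ± 0.13 in daidzein, 1.01 ± 0.11 in bisphenol A, 1.32 ± 0.48 in nonylphenol and 1.14 ± 0.037 in PPT. The first 3 principal components held 30.8%, 25.8% and 7.67% of the variance. The number of arrays limits the precision.

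**Figure D1:**
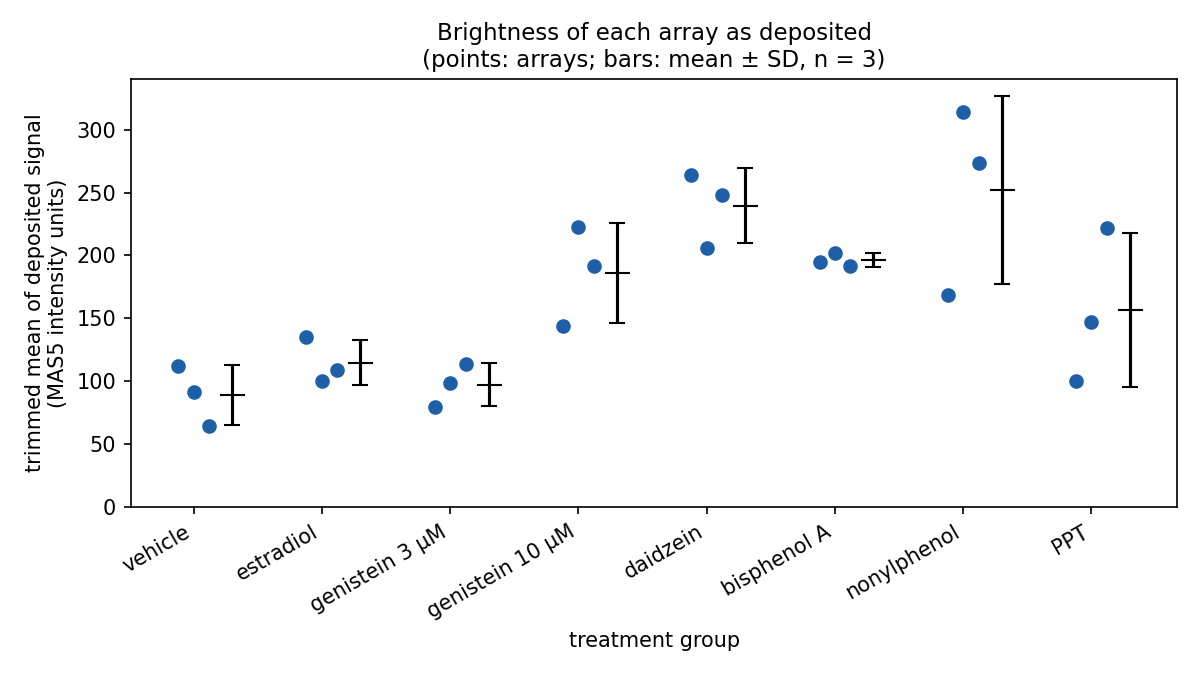
Brightness of each array, as the 2% trimmed mean of the deposited MAS5 signal, in the 8 groups of 3 arrays; points are arrays and bars are the mean ± SD. Means ran from 89.5 in vehicle to 252 in nonylphenol.

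Estradiol raised genes long used as markers of estrogen action and genes of cell division. CCN5, an estrogen-induced signalling protein gene, rose 24.4-fold, a log2 change of 4.61 ± 0.41 (SE, n = 3, limma adjusted p = 8.03e-09). PGR, the progesterone receptor, rose by 3.76 ± 0.34 (13.5-fold, adjusted p = 1.07e-08), and PDZK1, a scaffold protein, by 2.81 ± 0.21 (adjusted p = 5.64e-10). The 3 treated arrays lay above the 3 vehicle arrays for each of these genes. GPRC5A, a membrane receptor, fell by 3.53 ± 0.44 (adjusted p = 1.39e-06), APOD, a lipid carrier, fell by 2.60 ± 0.19 and SMAD6, an inhibitor of BMP signalling, fell by 2.92 ± 0.23. Vehicle signals of PGR were 2.37, 4.24 and 2.01 on the log2 scale, under the median of 5.72 over all probe sets. The vehicle mean of CCN5 was 4.40, also under that median. The folds of both genes against vehicle therefore rest on dim signals.

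Of 33 estrogen-induced genes tested, 24 rose, 2 fell and 7 did not pass in estradiol (26 changed when adjusted over the list alone), with a median log2 change of 0.80 (camera adjusted p = 3.36e-12). TFF1, a secreted mucosal peptide, rose by 1.26 ± 0.14, GREB1, a cofactor of the estrogen receptor, by 1.56 ± 0.24 and SIAH2, a ubiquitin ligase, by 1.65 ± 0.13, whereas MYC stood at −0.21 ± 0.18 (adjusted p = 0.431). All 12 estrogen-repressed genes tested fell (12 adjusted over the list alone, median −1.43, camera adjusted p = 1.84e-10), among them ESR1, the estrogen receptor itself, by −1.18 ± 0.13, ERBB2, a growth factor receptor, by −1.35 ± 0.19 and TSC22D3, a glucocorticoid-responsive gene, by −1.89 ± 0.16. DNA replication genes rose in 30 of 31 cases, with 1 not passing (31 adjusted over the list alone, median 1.29, camera adjusted p = 7.4e-28), and MCM7 of the replicative helicase rose by 1.79 ± 0.09. Mitosis genes rose in 34 of 35 cases, with 1 not passing (34 adjusted over the list alone, median 1.28, camera adjusted p = 4.36e-31), with NEK2, a centrosome kinase, at 2.08 ± 0.17 and TOP2A at 1.58 ± 0.13. Among G1/S genes 14 of 15 rose (14 adjusted over the list alone, median 1.23, camera adjusted p = 9.64e-11), and CKS1B, a partner of cyclin-dependent kinases, rose by 1.82 ± 0.12. DNA repair genes rose in 13 of 20 cases and fell in 1 (16 adjusted over the list alone, median 0.87, camera adjusted p = 1.35e-05), with BRCA1 at 1.80 ± 0.22. Cholesterol synthesis genes rose in 14 of 16 cases (14 adjusted over the list alone, median 1.00, camera adjusted p = 1.59e-10), with IDI1 at 1.72 ± 0.15 and FDPS at 1.70 ± 0.13. Of 13 cell cycle inhibitors 4 fell and none rose (5 adjusted over the list alone, camera adjusted p = 0.0157), with RBL2, a retinoblastoma-family gene, at −2.19 ± 0.25 and BTG1 at −1.71 ± 0.15, and the call was lost at adjusted p = 0.148 with an estimated correlation.

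Estradiol changed 2974 of 11108 probe sets, 1493 higher and 1481 lower, and 759 of them by more than 2-fold. CXCL12, a chemokine, rose by 0.69 ± 0.25 (SE, n = 3, limma adjusted p = 0.0422), and its adjusted p was 0.164 and 0.0564 without vehicle replicates 1 and 2 and 0.140 and 0.0883 without estradiol replicates 2 and 3.

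**Figure D2:**
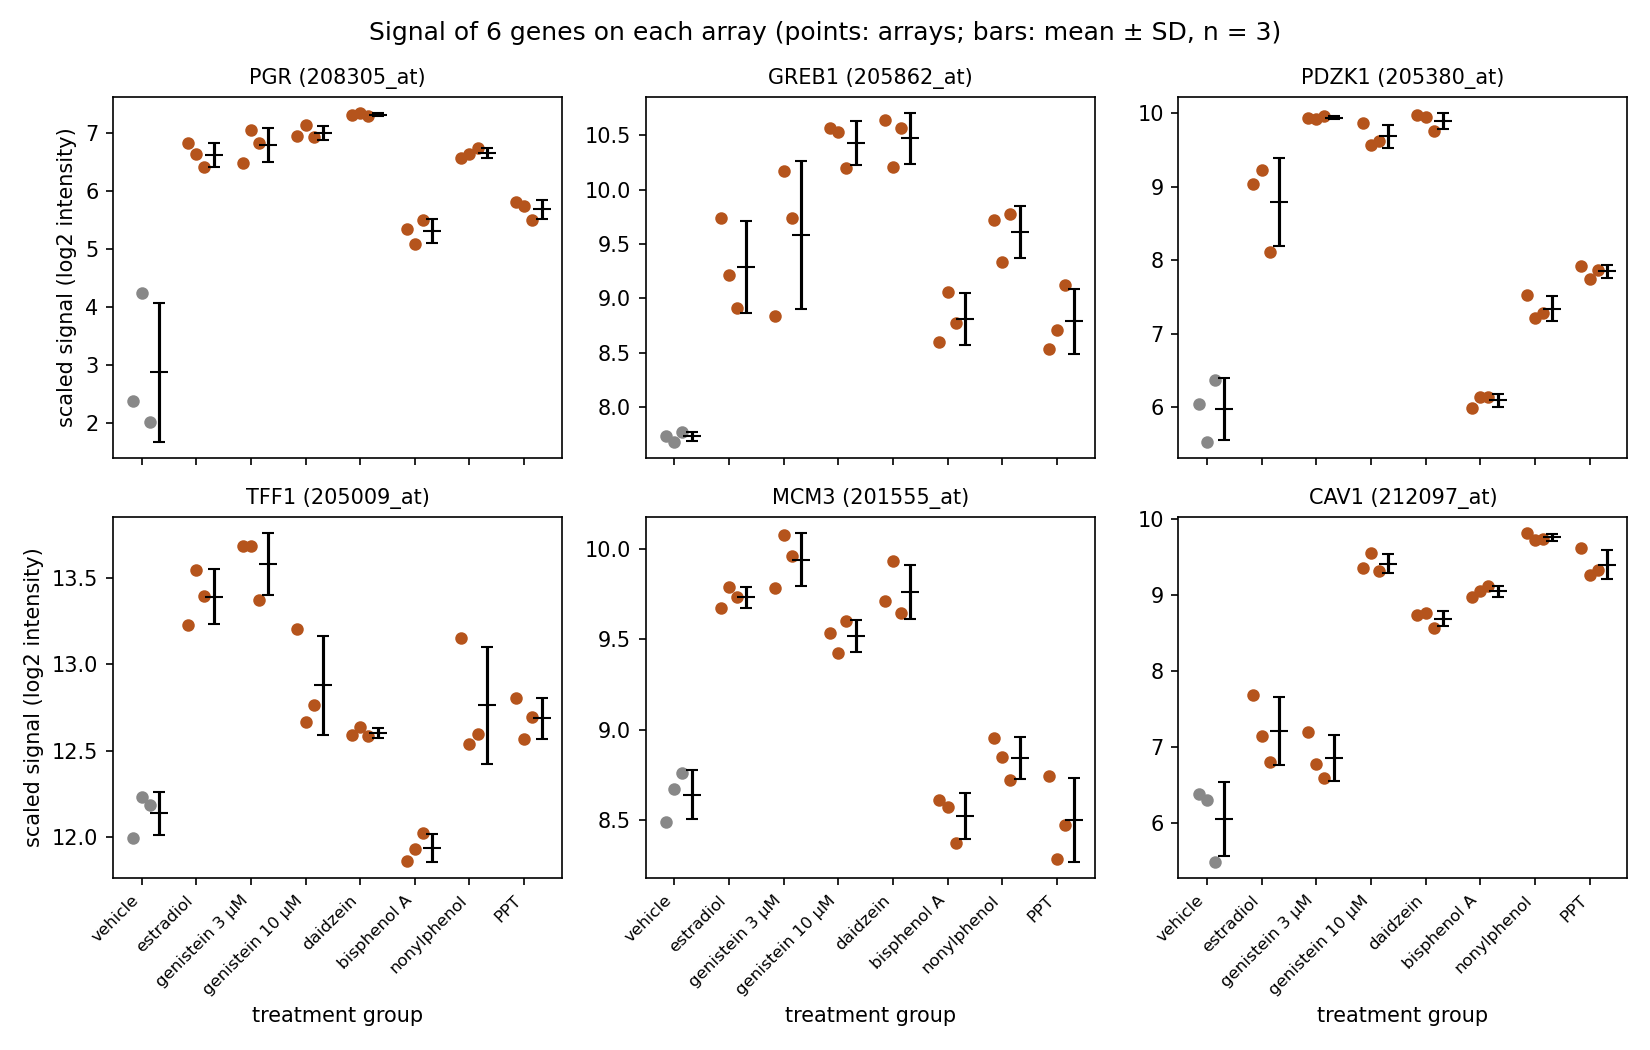
Log2 signal of 6 genes (PGR, GREB1, PDZK1, TFF1, MCM3 and CAV1) on each of the 24 arrays after scaling, by group; points are arrays and bars are the mean ± SD of 3. PGR lay between 5.09 and 5.51 in bisphenol A and between 2.01 and 4.24 in vehicle.

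Genistein at 3 µM raised estrogen-induced, cell division and cholesterol synthesis genes, the lists that rose with estradiol. PRSS23, a secreted protease, rose by 4.70 ± 0.33 (SE, n = 3, limma adjusted p = 1.07e-10), PDZK1 by 3.95 ± 0.21 (adjusted p = 2.82e-12) and PGR by 3.92 ± 0.34 (adjusted p = 2.69e-09). FHL2, a transcriptional cofactor, rose by 3.92 ± 0.34. ESR1 fell by 1.52 ± 0.13 and BLNK, a B-cell adaptor gene on the estrogen-repressed list, fell by 2.16 ± 0.19. Of 33 estrogen-induced genes, 24 rose and 3 fell (31 adjusted over the list alone, median 1.18, camera adjusted p = 9.24e-14). All 12 estrogen-repressed genes fell (12 adjusted over the list alone, median −1.61, camera adjusted p = 1.11e-09). DNA replication genes rose in 30 of 31 cases (31 adjusted over the list alone, median 1.34, camera adjusted p = 1.1e-24), with MCM6 at 1.93 ± 0.13 and RRM2, which supplies deoxynucleotides, at 2.01 ± 0.15. Mitosis genes rose in 34 of 35 (35 adjusted over the list alone, median 1.33, camera adjusted p = 9.11e-29), with PLK1, a mitotic kinase, at 1.59 ± 0.13. G1/S genes rose in 13 of 15 (15 adjusted over the list alone, camera adjusted p = 1.11e-09), DNA repair genes in 12 of 20 with 2 falls (14 adjusted over the list alone, camera adjusted p = 0.00015) and cholesterol synthesis genes in 14 of 16 (14 adjusted over the list alone, camera adjusted p = 4.35e-10). Of 14 oxidative stress genes 8 rose and 2 fell (11 adjusted over the list alone, median 0.40, camera adjusted p = 0.0139), with GCLM, of glutathione synthesis, at 1.15 ± 0.22 and TXNRD1, a thioredoxin reductase, at 0.82 ± 0.12. Of 13 cell cycle inhibitors 6 fell and 1 rose (7 adjusted over the list alone, camera adjusted p = 0.0215, adjusted p = 0.161 with an estimated correlation). In total 3551 probe sets changed, 1654 higher and 1897 lower.

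At 10 µM, genistein also raised estrogen-induced and cell division genes. CCN5 rose 56.1-fold, by 5.81 ± 0.41 (SE, n = 3, limma adjusted p = 9.34e-11), PRSS23 by 5.62 ± 0.33 and NPY1R, a neuropeptide Y receptor, by 4.09 ± 0.19. PGR rose by 4.14 ± 0.34 (adjusted p = 1.27e-09). SPDEF, a transcription factor of luminal cells, fell by 2.91 ± 0.15 and APOD fell by 3.24 ± 0.19. Of 33 estrogen-induced genes 24 rose and 2 fell (27 adjusted over the list alone, median 1.04, camera adjusted p = 1.64e-10). Among the estrogen-repressed genes 11 of 12 genes fell (12 adjusted over the list alone, median −1.27, camera adjusted p = 9.26e-08). DNA replication genes rose in 30 of 31 (30 adjusted over the list alone, median 1.19, camera adjusted p = 1.05e-16), with GMNN, a regulator of replication licensing, at 2.01 ± 0.13. Mitosis genes rose in 33 of 35 (33 adjusted over the list alone, camera adjusted p = 2.66e-19), G1/S genes in 12 of 15 (12 adjusted over the list alone, camera adjusted p = 3.84e-06) and DNA repair genes in 12 of 20 with 1 fall (14 adjusted over the list alone, camera adjusted p = 0.000395), with CHEK1, a checkpoint kinase, at 2.18 ± 0.21. Cholesterol synthesis genes rose in 13 of 16 and fell in 1 (14 adjusted over the list alone, camera adjusted p = 1.53e-05), with FDPS at 2.14 ± 0.13. Unfolded protein response genes rose in 10 of 18 and fell in 2 (12 adjusted over the list alone, median 0.54, camera adjusted p = 0.0131), with PDIA6, a protein disulfide isomerase, at 1.63 ± 0.16. In total 5024 probe sets changed, 2488 higher and 2536 lower. With array brightness as a covariate, chosen after seeing the data, 3089 did.

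Daidzein raised estrogen-induced and cell division genes. PRSS23 rose by 5.56 ± 0.33 (SE, n = 3, limma adjusted p = 6.79e-12), PGR 21.8-fold, by 4.45 ± 0.34 (adjusted p = 4.74e-10), and PDZK1 by 3.91 ± 0.21. CYP1A1, an oxidase of xenobiotic metabolism, fell by 2.82 ± 0.33, and SELENBP1, a selenium-binding protein gene, fell by 2.34 ± 0.13. TFF1 was higher by 0.47 ± 0.14 (adjusted p = 0.0106), and without vehicle replicate 1 its adjusted p was 0.0509. Of 33 estrogen-induced genes 24 rose and 2 fell (27 adjusted over the list alone, median 1.23, camera adjusted p = 1.82e-11). All 12 estrogen-repressed genes fell (12 adjusted over the list alone, median −1.27, camera adjusted p = 4.45e-08). DNA replication genes rose in 30 of 31 (30 adjusted over the list alone, median 1.36, camera adjusted p = 2.66e-19), mitosis genes in 33 of 35 (33 adjusted over the list alone, camera adjusted p = 7.81e-21), with MAD2L1, of the spindle checkpoint, at 2.57 ± 0.18, and G1/S genes in 14 of 15 (14 adjusted over the list alone, camera adjusted p = 1.16e-07). DNA repair genes rose in 14 of 20 and fell in 1 (15 adjusted over the list alone, camera adjusted p = 7.04e-05), with BRCA1 at 2.29 ± 0.22. Cholesterol synthesis genes rose in 9 of 16 and fell in 1 (11 adjusted over the list alone, camera adjusted p = 0.00306, adjusted p = 0.063 with an estimated correlation). In total 5008 probe sets changed, 2526 higher and 2482 lower, and 2349 did with array brightness as a covariate.

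Bisphenol A raised some estrogen-induced genes while cell division genes did not rise as a group. CAV1, a structural protein of caveolae, rose 7.91-fold, by 2.98 ± 0.20 (SE, n = 3, limma adjusted p = 2.87e-10), PMAIP1, a mediator of cell death, by 2.75 ± 0.36 and PRSS23 by 2.68 ± 0.33 (adjusted p = 5.07e-06). CAV1 also rose with PPT, by 3.34, and differed by 2.55 between the genistein doses, so its rise may not be particular to bisphenol A. PGR rose 5.44-fold, by 2.44 ± 0.34 (adjusted p = 2.57e-05). Its mean log2 signal was 2.87 in vehicle and 5.32 with bisphenol A, both under the median over all probe sets. The vehicle means of PMAIP1 and PRSS23 were 3.75 and 4.22, also under that median. The sizes of the rises of PGR, PMAIP1 and PRSS23 therefore rest on dim signals. CDC45, a replication factor, fell by 3.13 ± 0.28 (adjusted p = 7.28e-08) to a dim mean signal of 2.19 on the log2 scale. TIMP3, a protease inhibitor, fell by 1.75 ± 0.19. GREB1 rose by 1.08 ± 0.24 (adjusted p = 0.00221), whereas TFF1 stood at −0.20 ± 0.14 (adjusted p = 0.318) and PDZK1 at 0.11 ± 0.21 (adjusted p = 0.724). TFF1 was bright, at a vehicle mean of 12.1 on the log2 scale. Other bright probe sets, matched in signal to ribosomal protein genes, had a median of −0.40 in this comparison. The TFF1 value may therefore depend on the scaling. The estrogen-induced list had 11 of 33 genes that rose and 6 that fell (18 adjusted over the list alone, median 0.11), and the list did not pass (camera adjusted p = 0.206). Of 12 estrogen-repressed genes 4 fell and 2 rose (6 adjusted over the list alone, camera adjusted p = 0.335). DNA replication genes fell in 8 of 31 cases and rose in none (8 adjusted over the list alone, median −0.11, camera adjusted p = 0.105). Mitosis genes fell in 12 of 35 and rose in 1 (17 adjusted over the list alone, median −0.29, camera adjusted p = 0.000166, adjusted p = 0.191 with an estimated correlation), with PRC1, which bundles spindle microtubules, at −0.85 ± 0.10. G1/S genes rose in 2 of 15 and fell in 5 (8 adjusted over the list alone, camera adjusted p = 0.539), DNA repair genes rose in 2 of 20 (1 adjusted over the list alone, camera adjusted p = 0.48) and cholesterol synthesis genes rose in 5 of 16 and fell in 2 (9 adjusted over the list alone, camera adjusted p = 0.0837), with SC5D at 1.17 ± 0.13. Of 13 cell cycle inhibitors 5 rose (5 adjusted over the list alone, camera adjusted p = 0.0214, adjusted p = 0.161 with an estimated correlation). Of 18 glycolysis genes 6 fell (6 adjusted over the list alone, camera adjusted p = 0.0109, adjusted p = 0.148 with an estimated correlation), with PFKL, a phosphofructokinase, at −1.22 ± 0.18.

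Bisphenol A changed 2838 probe sets, 1575 higher and 1263 lower. Of these, 1646 also differed in the same direction between the genistein doses. Much of this response may thus not be particular to bisphenol A, and a batch of arrays cannot be told apart from the compounds. With array brightness as a covariate 434 changed and the calls of GREB1, the cell cycle inhibitors and glycolysis ended, the last also under quantile normalization. Without vehicle replicate 3 the count was 1862.

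Nonylphenol raised many estrogen-induced genes and some cell division genes. PGR rose 13.8-fold, by 3.78 ± 0.34 (SE, n = 3, limma adjusted p = 2.16e-08), CAV1 by 3.69 ± 0.20 (adjusted p = 1.23e-11), CCN5 by 3.52 ± 0.41 and NPY1R by 3.18 ± 0.19. APOD fell by 2.82 ± 0.19 and ERBB2 fell by 1.45 ± 0.19. Of 33 estrogen-induced genes 19 rose and 3 fell (22 adjusted over the list alone, median 0.63, camera adjusted p = 1.3e-05). Of 12 estrogen-repressed genes 7 fell (7 adjusted over the list alone, median −0.68, camera adjusted p = 0.00601, adjusted p = 0.0811 with an estimated correlation), with ID2, an inhibitor of differentiation, at −0.96 ± 0.19. DNA replication genes rose in 19 of 31 and fell in 1 (22 adjusted over the list alone, median 0.58, camera adjusted p = 6.81e-07, adjusted p = 0.0747 with an estimated correlation), with MCM6 at 1.12 ± 0.13 and MCM3 at 0.20 ± 0.12 (adjusted p = 0.2). Mitosis genes rose in 19 of 35 and fell in 1 (20 adjusted over the list alone, median 0.42, camera adjusted p = 2.7e-05, adjusted p = 0.149 with an estimated correlation), with MAD2L1 at 1.72 ± 0.18. G1/S genes rose in 7 of 15 (7 adjusted over the list alone, camera adjusted p = 0.0172, adjusted p = 0.137 with an estimated correlation). DNA repair genes rose in 9 of 20 (9 adjusted over the list alone, camera adjusted p = 0.0116, adjusted p = 0.0986 with an estimated correlation). Cholesterol synthesis genes rose in 12 of 16 and fell in 1 (13 adjusted over the list alone, median 0.96, camera adjusted p = 3.56e-07), with MSMO1, a sterol demethylase, at 1.93 ± 0.14. In total 4226 probe sets changed, 2150 higher and 2076 lower, and 1073 did with array brightness as a covariate.

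PPT raised PGR and some other estrogen-induced genes, and genes of adhesion and the cytoskeleton. ANXA1, a calcium-dependent membrane-binding protein, rose 20.5-fold, by 4.36 ± 0.26 (SE, n = 3, limma adjusted p = 9.87e-12), LOXL2, which crosslinks collagen, by 3.94 ± 0.29 and CAV1 by 3.34 ± 0.20. CAV1 also rose with bisphenol A, by 2.98. Between the genistein doses CAV1 and ANXA1 differed by 2.55 and 2.28. These rises may thus not be particular to PPT, and a batch of arrays cannot be told apart from the compounds. PGR rose 7.04-fold, by 2.82 ± 0.34 (adjusted p = 1.44e-06), GREB1 by 1.06 ± 0.24 and TFF1 by 0.55 ± 0.14 (adjusted p = 0.0051). The PGR fold rests on dim signals, at means of 2.87 in vehicle and 5.69 with PPT on the log2 scale. MYB, a transcription factor gene on the estrogen-induced list, fell by 1.29 ± 0.18. Estrogen-induced genes rose in 14 of 33 cases and fell in 9 (23 adjusted over the list alone, median 0.22, camera adjusted p = 0.294). Of 12 estrogen-repressed genes 3 fell and 1 rose (4 adjusted over the list alone, camera adjusted p = 0.121). Mitosis genes rose in 20 of 35 (22 adjusted over the list alone, median 0.39, camera adjusted p = 6.77e-05, adjusted p = 0.162 with an estimated correlation), with KIF23, a motor of cytokinesis, at 1.33 ± 0.23. DNA replication genes rose in 3 of 31 and fell in 1 (1 adjusted over the list alone, median 0.13, camera adjusted p = 0.594), with MCM3 at −0.14 ± 0.12 (adjusted p = 0.403). G1/S genes rose in 4 of 15 and fell in 3 (8 adjusted over the list alone, camera adjusted p = 0.964). DNA repair genes rose in 3 of 20 (2 adjusted over the list alone, camera adjusted p = 0.48). Cholesterol synthesis genes rose in 10 of 16 and fell in 1 (13 adjusted over the list alone, median 0.76, camera adjusted p = 2.95e-05), with FDPS at 1.56 ± 0.13. Adhesion and cytoskeleton genes rose in 9 of 21 and fell in 1 (11 adjusted over the list alone, median 0.34, camera adjusted p = 0.000535), with ANXA2 at 1.03 ± 0.10. Of 13 cell cycle inhibitors 8 rose and 1 fell (9 adjusted over the list alone, camera adjusted p = 0.1), with CDKN1A at 0.87 ± 0.16 and GADD45A at 1.61 ± 0.22. In total 3518 probe sets changed, 1845 higher and 1673 lower, and 2343 did in a fit on the 6 arrays of both groups alone.

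**Figure D3:**
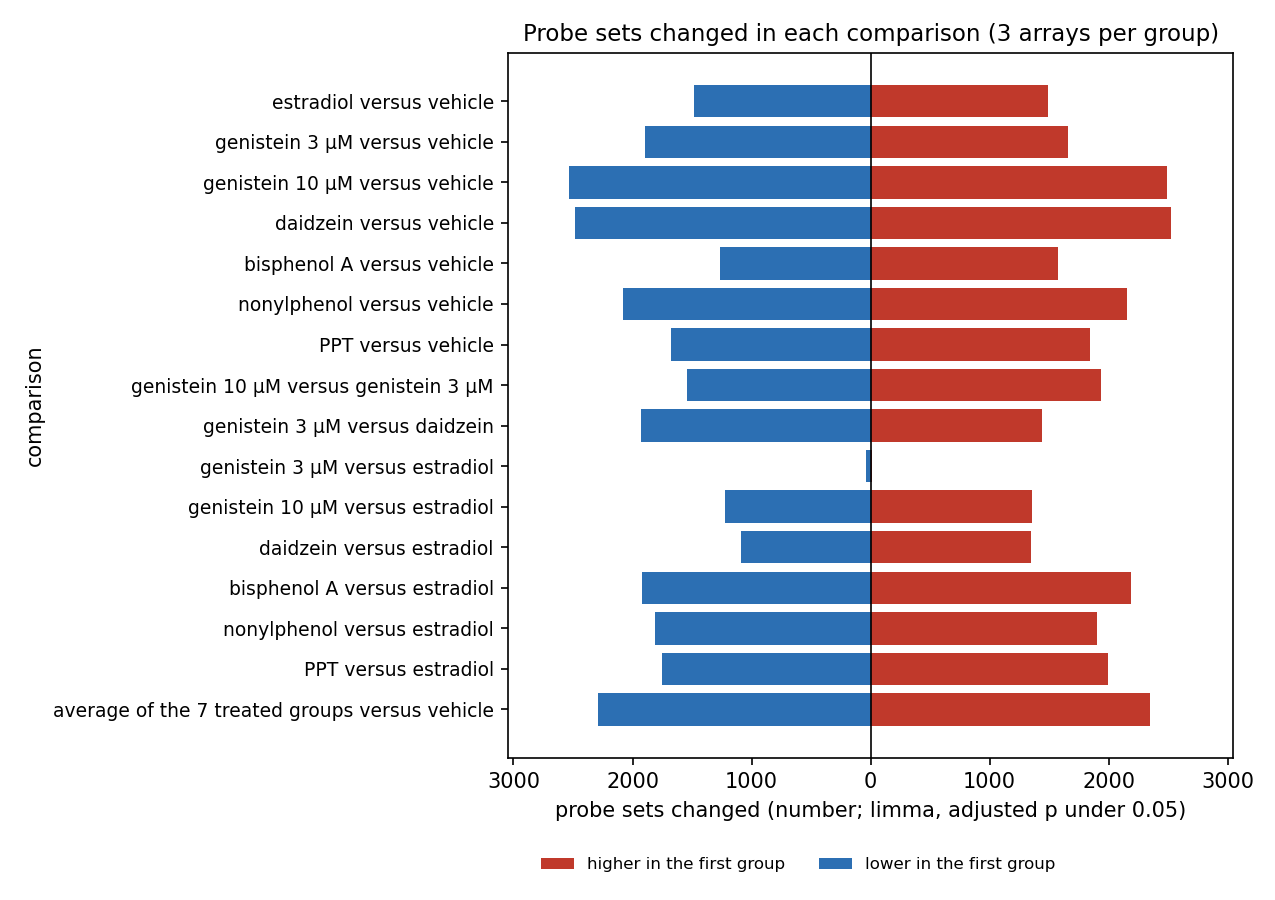
Probe sets changed in each comparison (limma, Benjamini-Hochberg adjusted p under 0.05), higher to the right and lower to the left, among 11108 tested. Genistein 3 µM against estradiol had 44 and genistein 10 µM against vehicle had 5024.

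Other lists shifted with several compounds. Cytosolic ribosomal protein genes fell in 7 of 16 cases in estradiol and in genistein 3 µM, in all 16 in genistein 10 µM and daidzein, in 12 in bisphenol A and in 13 in nonylphenol and PPT (9, 11, 16, 16, 14, 15 and 13 adjusted over the list alone). Their medians were −0.28, −0.28, −0.69, −0.90, −0.57, −0.61 and −0.51 in that order (camera adjusted p from 1.11e-09 to 0.00555, adjusted p from 0.0805 to 0.399 with an estimated correlation), and all these calls ended under quantile normalization, where the bisphenol A median was 0.037. RPL18 stood at −0.94 ± 0.11 in daidzein (SE, n = 3), and its call also ended there. The groups with the larger falls were those with the brighter arrays, at group means from 156 to 252 against 89.5 in vehicle. Luminal epithelial genes fell in 8, 8, 11, 10, 4, 7 and 10 of 14 cases, and 1 rose in daidzein, bisphenol A and PPT (8, 10, 12, 12, 6, 8 and 11 adjusted over the list alone), with medians of −0.45, −0.46, −0.95, −0.75, −0.19, −0.53 and −0.57 and camera adjusted p from 2.46e-05 to 0.0201, and with an estimated correlation only genistein 10 µM passed (adjusted p = 0.0458, others from 0.0507 to 0.231). Quantile normalization ended the calls in bisphenol A and nonylphenol, and array brightness as a covariate that in bisphenol A. Chaperone genes rose in 12 of 18 in estradiol, 14 in genistein 3 µM, 10 in genistein 10 µM, 8 in daidzein and 8 in PPT, and 1 fell in genistein 10 µM and in daidzein (15, 16, 11, 10 and 9 adjusted over the list alone), with camera adjusted p of 3.84e-06, 2.31e-06, 0.00555, 0.0239 and 0.0255 and adjusted p of 0.0632, 0.0605, 0.233, 0.316 and 0.321 with an estimated correlation. Fatty acid synthesis genes rose in 5 of 8 in estradiol (5 adjusted over the list alone, camera adjusted p = 0.00306) and in 5 of 8 in genistein 3 µM (5 adjusted over the list alone, camera adjusted p = 0.00536, adjusted p = 0.0609 with an estimated correlation), with SCD, a desaturase, at 1.44 ± 0.15 in both. TGF-beta and BMP genes fell in 6 and 7 of 15 in estradiol and genistein 3 µM, where 1 rose (6 and 8 adjusted over the list alone, camera adjusted p = 0.0433 and 0.0421, adjusted p = 0.0849 and 0.083 with an estimated correlation), and BAMBI, a decoy receptor, stood at −1.14 ± 0.14 and −1.97 ± 0.14. Both list calls ended under quantile normalization. Ribosome biogenesis genes rose in 6, 4 and 7 of 15 in estradiol, genistein 3 µM and genistein 10 µM (6, 4 and 7 adjusted over the list alone, camera adjusted p = 0.0425, 0.0476 and 0.0421, adjusted p = 0.23, 0.233 and 0.228 with an estimated correlation), and array brightness as a covariate ended these calls.

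Several lists passed in no comparison with vehicle. Camera adjusted p ranged from 0.269 to 0.584 for pro-apoptotic genes, from 0.0545 to 0.841 for anti-apoptotic genes, from 0.0777 to 0.654 for p53 targets and from 0.567 to 0.993 for aryl hydrocarbon receptor targets. It ranged from 0.32 to 0.892 for oxidative phosphorylation, from 0.151 to 0.652 for growth factor signalling, from 0.317 to 0.863 for interferon response and from 0.0625 to 0.832 for nuclear receptors and coregulators. Markers of other cell types were few among tested genes: 5 of 18 fibroblast genes (camera adjusted p from 0.209 to 0.964), 4 of 18 leukocyte genes (from 0.208 to 0.658) and 2 of 16 basal epithelial genes, too few to test.

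**Figure D4:**
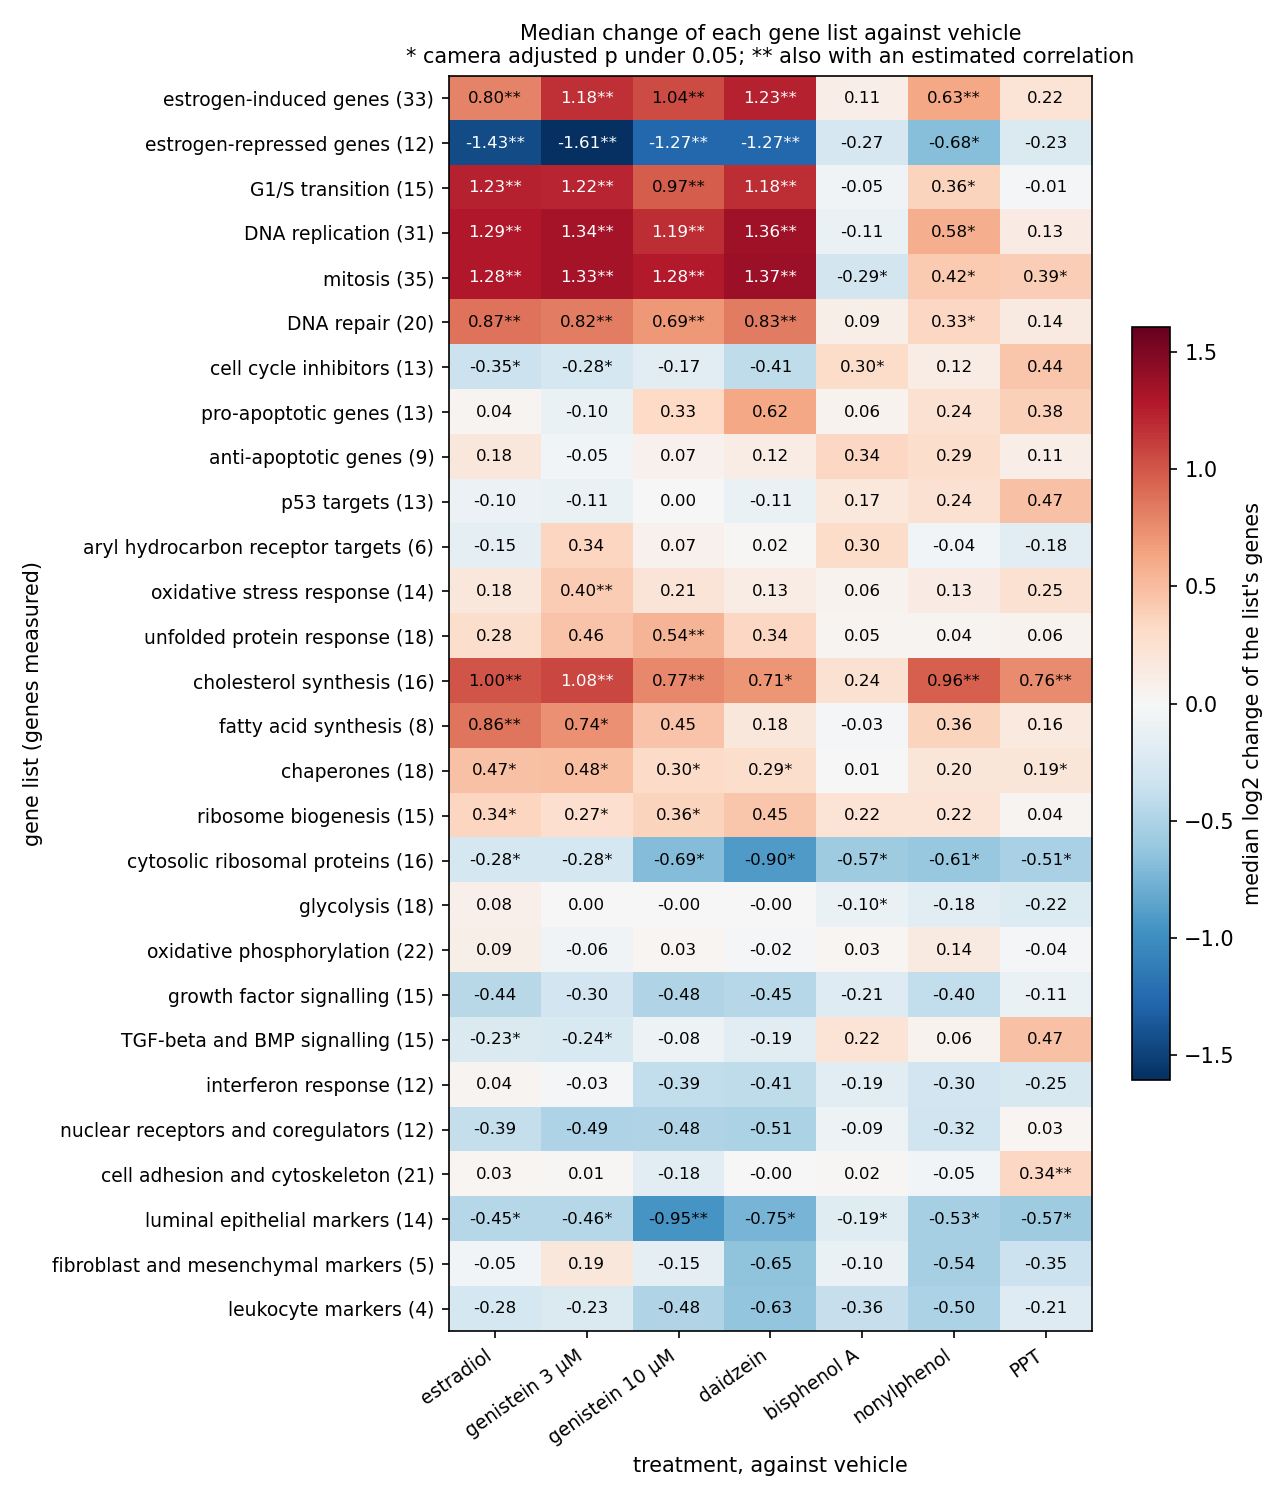
Median log2 change (color and number) of each fixed gene list with its genes measured (vertical axis) in the 7 comparisons with vehicle (horizontal axis); 1 star marks a camera adjusted p under 0.05 and a pair of stars one that also held with an estimated correlation. DNA replication stood at 1.29 in estradiol and −0.11 in bisphenol A, and ribosomal proteins stood at −0.57 in bisphenol A, or 0.037 under quantile normalization.

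The median log2 change of the estrogen-induced genes per array, less that of vehicle, was 0.88 in estradiol, 1.13 in genistein 3 µM, 1.01 in genistein 10 µM, 1.22 in daidzein, 0.17 in bisphenol A, 0.67 in nonylphenol and 0.24 in PPT (n = 3 arrays per group). The two-sided exact permutation p was 0.1 for each, the smallest that 3 arrays against 3 allow.

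Genistein at its higher dose differed from its lower dose in CAV1, at 2.55 ± 0.20 (SE, n = 3, limma adjusted p = 6.44e-09), in CAV2, another caveolin, at 2.32 ± 0.22, and in ANXA1, at 2.28 ± 0.26. FASN, the fatty acid synthase, fell by 2.16 ± 0.29. CAV1 also rose with bisphenol A, nonylphenol and PPT, by 2.98, 3.69 and 3.34 against vehicle, and the higher dose differed from daidzein in 11 probe sets, so these differences may not be due to dose. TFF1 fell by 0.70 ± 0.14 (adjusted p = 0.000823) and GREB1 rose by 0.85 ± 0.24 (adjusted p = 0.00967), while PGR differed by 0.22 (95% interval −0.49 to 0.92) and PDZK1 by −0.25 (−0.68 to 0.17). Estrogen-induced genes rose in 7 of 33 and fell in 7 (14 adjusted over the list alone, camera adjusted p = 0.837), where the list median of 0.04 and the test differed in sign. DNA replication genes fell in 6 of 31 and rose in 2 (8 adjusted over the list alone, camera adjusted p = 0.0705). Adhesion genes rose in 9 of 21 and fell in 2 (12 adjusted over the list alone, median 0.31, camera adjusted p = 0.022, adjusted p = 0.0544 with an estimated correlation). Ribosomal protein genes fell in 9 of 16 (10 adjusted over the list alone, camera adjusted p = 0.000146, adjusted p = 0.293 with an estimated correlation), with a median of −0.32 that was 0.046 under quantile normalization. Luminal genes fell in 5 of 14 and rose in 2 (7 adjusted over the list alone, camera adjusted p = 0.0322, adjusted p = 0.297 with an estimated correlation). In total 3480 probe sets differed, 1939 higher and 1541 lower at the higher dose, and 1460 did with array brightness as a covariate. That covariate ended the calls of TFF1, GREB1 and both of the last lists. Quantile normalization ended those of TFF1 and the luminal list, and without genistein 3 µM replicate 1 GREB1 had an adjusted p of 0.112.

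Genistein, which carries a hydroxyl group at position 5 that daidzein lacks, was compared with it at 3 µM against 1 µM, so the doses differed. Genistein at 10 µM differed from daidzein in only 11 probe sets, so the differences at 3 µM may be due neither to structure nor to dose. A batch of arrays cannot be told apart from the compounds. TFF1 was higher with genistein by 0.98 ± 0.14 (SE, n = 3, limma adjusted p = 2.99e-05) and GREB1 was lower, at −0.89 ± 0.24 (adjusted p = 0.00742). Cholesterol synthesis genes were higher in 9 of 16 and lower in 1 (11 adjusted over the list alone, median 0.55, camera adjusted p = 0.00016), with DHCR7, a sterol reductase, at 1.01 ± 0.15. CAV1 was lower with genistein, at −1.83 ± 0.20. PGR differed by −0.52 ± 0.34 (95% interval −1.23 to 0.18), PDZK1 by 0.05 ± 0.21 (−0.38 to 0.47) and MCM3 by 0.18 ± 0.12 (−0.07 to 0.43). Per-array medians differed by −0.088 for estrogen-induced genes (−0.26 to 0.0845), by −0.051 for DNA replication (−0.215 to 0.113) and by −0.0033 for mitosis (−0.161 to 0.155). Ribosomal protein genes were higher in 13 of 16 (13 adjusted over the list alone, median 0.53, camera adjusted p = 1.19e-08, adjusted p = 0.123 with an estimated correlation), and under quantile normalization the median was −0.066. In total 3371 probe sets differed, 1440 higher and 1931 lower with genistein, against 467 with array brightness as a covariate and 2164 without daidzein replicate 1. That covariate ended the calls of TFF1 and GREB1, quantile normalization ended that of TFF1 (0.20), and without genistein 3 µM replicate 1 GREB1 had an adjusted p of 0.0872.

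Genistein at 3 µM and estradiol differed in few genes. SMAD6 was higher with genistein by 1.84 ± 0.23 (SE, n = 3, limma adjusted p = 0.000472), LYPD3 was lower, at −1.29 ± 0.20 (adjusted p = 0.00505), PLK2, a stress-responsive kinase, at −0.97 ± 0.16 (adjusted p = 0.00579) and BAMBI at −0.83 ± 0.14. PDZK1 was higher by 1.15 ± 0.21 (adjusted p = 0.0132), with an adjusted p of 0.105 without estradiol replicate 3 and 0.0678 without genistein 3 µM replicate 1. PGR differed by 0.17 (95% interval −0.54 to 0.87), TFF1 by 0.19 (−0.11 to 0.49), GREB1 by 0.29 (−0.21 to 0.79) and MCM3 by 0.21 (−0.04 to 0.46). Estrogen-induced genes had 1 of 33 higher (10 adjusted over the list alone, median 0.18, camera adjusted p = 5.82e-05, adjusted p = 0.0682 with an estimated correlation). Oxidative stress genes had a median of 0.15 with none of 14 changed (2 adjusted over the list alone, camera adjusted p = 0.0113). Oxidative phosphorylation genes had one of −0.17 with 1 of 22 lower (2 adjusted over the list alone, camera adjusted p = 0.00149, adjusted p = 0.198 with an estimated correlation). In total 44 probe sets differed, 8 higher and 36 lower, and 1201 had an unadjusted p under 0.05. The count was 10 without estradiol replicate 1, 7 without estradiol replicate 3, 9, 14 and 170.0 without genistein 3 µM replicates 1, 2 and 3, 24 with array brightness as a covariate or with no filter, and 0 in a fit on the 6 arrays.

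Genistein at 10 µM and daidzein were each higher than estradiol in GPRC5A, by 2.94 ± 0.44 and 2.64 ± 0.44 (SE, n = 3, limma), and in COL18A1, a basement membrane collagen, by 2.71 ± 0.29 and 2.61 ± 0.29. GPRC5A was dim in estradiol, at a mean of 4.14 on the log2 scale. It was also higher with bisphenol A, nonylphenol and PPT, by 4.22, 3.78 and 4.27. Its difference may thus not be particular to the isoflavones, and a batch of arrays cannot be told apart from the compounds. GREB1 was higher by 1.14 ± 0.24 and 1.18 ± 0.24, and PDZK1 by 0.89 ± 0.21 and 1.10 ± 0.21. PGR differed by 0.38 (95% interval −0.32 to 1.09) and 0.69 (−0.01 to 1.39). TFF1 was lower, at −0.51 ± 0.14 and −0.79 ± 0.14, calls that ended under quantile normalization and with array brightness as a covariate. The genistein call had an adjusted p of 0.0668 without estradiol replicate 2 and 0.0826 without genistein 10 µM replicate 2. Adhesion genes were higher in 10 of 21 with genistein and 9 of 21 with daidzein, and lower in 1 and 3 (11 and 12 adjusted over the list alone, camera adjusted p = 0.000156 and 0.00625), with CAV1 at 2.19 ± 0.20 and 1.48 ± 0.20. Cholesterol synthesis genes were lower with daidzein in 8 of 16 and higher in 1 (12 adjusted over the list alone, median −0.44, camera adjusted p = 3.88e-05). Fatty acid synthesis genes were lower in 4 of 8 and higher in 1 (5 adjusted over the list alone, camera adjusted p = 0.0117, adjusted p = 0.0928 with an estimated correlation). Estrogen-induced genes were higher with daidzein in 15 of 33 and lower in 3 (20 adjusted over the list alone, camera adjusted p = 0.00357, adjusted p = 0.182 with an estimated correlation). Unfolded protein response genes were higher with genistein in 7 of 18 (7 adjusted over the list alone, camera adjusted p = 0.0313, adjusted p = 0.0682 with an estimated correlation). Ribosomal protein genes were lower in 9 and 14 of 16 (13 and 16 adjusted over the list alone, camera adjusted p = 3.73e-06 and 3.55e-11, adjusted p = 0.196 and 0.0682 with an estimated correlation), with medians of −0.40 and −0.56 that were 0.011 and 0.056 under quantile normalization. Luminal genes were lower in 6 and 4 of 14 and higher in 1 with each (7 and 7 adjusted over the list alone, camera adjusted p = 0.00149 and 0.034, adjusted p = 0.142 and 0.297 with an estimated correlation). In total 2581 and 2437 probe sets differed from estradiol, and 1605 and 833 did with array brightness as a covariate, which ended the daidzein call of GREB1. The daidzein luminal call ended with it and under quantile normalization. For genistein the count was 1719 without estradiol replicate 2, 1581 without estradiol replicate 3 and 1537 without genistein 10 µM replicate 2, and for daidzein it was 1532 without estradiol replicate 3 and 1429 without daidzein replicate 1.

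Bisphenol A lay below estradiol in genes of the cell cycle. CDC45 was 60.9-fold lower, at −5.93 ± 0.28 (SE, n = 3, limma adjusted p = 1.71e-13), MCM7 stood at −2.19 ± 0.09 and CDC20, an activator of mitotic exit, at −2.24 ± 0.14. The CDC45 signal with bisphenol A was dim, at a mean of 2.19 on the log2 scale, so the size of its fold rests on a dim signal. PGR was lower, at −1.31 ± 0.34 (adjusted p = 0.00378), TFF1 at −1.46 ± 0.14 and PDZK1 at −2.70 ± 0.21, while GREB1 differed by −0.48 ± 0.24 (adjusted p = 0.125). ESR1 was higher by 0.93 ± 0.13. All 31 DNA replication genes and all 35 mitosis genes were lower (31 and 35 adjusted over the list alone, medians −1.53 and −1.62, camera adjusted p = 8.22e-26 and 5.95e-32), as were 13 of 15 G1/S genes (13 adjusted over the list alone, camera adjusted p = 5.34e-09) and 14 of 20 DNA repair genes with 2 higher (18 adjusted over the list alone, camera adjusted p = 0.000972). Estrogen-induced genes were lower in 21 of 33 and higher in 3 (25 adjusted over the list alone, median −0.75, camera adjusted p = 9.2e-08). Estrogen-repressed genes were higher in 10 of 12 (10 adjusted over the list alone, median 1.13, camera adjusted p = 2.21e-06). Cholesterol synthesis genes were lower in 12 of 16 and higher in 1 (15 adjusted over the list alone, camera adjusted p = 2.32e-06), with ACAT2 at −1.43 ± 0.11. Fatty acid synthesis genes were lower in 5 of 8 (5 adjusted over the list alone, camera adjusted p = 0.00219). Cell cycle inhibitors were higher in 7 of 13 (7 adjusted over the list alone, camera adjusted p = 0.000211). Chaperones were lower in 13 of 18, glycolysis genes in 11 of 18 with 3 higher, and TGF-beta and BMP genes higher in 7 of 15 with 1 lower (13, 16 and 8 adjusted over the list alone, camera adjusted p = 0.000156, 0.022 and 0.0341), and these had adjusted p = 0.147, 0.198 and 0.0773 with an estimated correlation. Quantile normalization ended the last pair of calls, and array brightness as a covariate the last one. In total 4114 probe sets differed, 2191 higher and 1923 lower.

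Nonylphenol and PPT also lay below estradiol in cell cycle genes. MCM7 stood at −1.37 ± 0.09 and −1.65 ± 0.09 (SE, n = 3, limma), and CCNA2, cyclin A2, at −1.56 ± 0.19 and −1.61 ± 0.19. DNA replication genes were lower in 24 and 30 of 31 (28 and 30 adjusted over the list alone, medians −0.77 and −1.28, camera adjusted p = 4.72e-16 and 1.49e-26), mitosis genes in 30 and 33 of 35 (33 and 34 adjusted over the list alone, medians −0.84 and −0.89, camera adjusted p = 2.11e-19 and 1.49e-20) and G1/S genes in 10 and 12 of 15 (10 and 12 adjusted over the list alone, camera adjusted p = 1.57e-05 and 2.3e-09). Estrogen-induced genes were lower in 17 and 19 of 33 and higher in 4 and 1 (23 and 25 adjusted over the list alone, camera adjusted p = 0.00334 and 3.25e-10), and the nonylphenol call had an adjusted p = 0.182 with an estimated correlation. Estrogen-repressed genes were higher in 8 and 10 of 12 (8 and 11 adjusted over the list alone, camera adjusted p = 0.000156 and 4.41e-06). Cell cycle inhibitors were higher in 8 and 9 of 13, and 1 was lower with PPT (8 and 10 adjusted over the list alone, camera adjusted p = 0.000184 and 0.000165). PGR differed by 0.03 (95% interval −0.68 to 0.73) with nonylphenol and by −0.94 ± 0.34 (adjusted p = 0.0356) with PPT, a call with an adjusted p of 0.110 and 0.0792 without estradiol replicates 1 and 2 and of 0.0504, 0.0652 and 0.105 without PPT replicates 1, 2 and 3. TFF1 was lower at −0.63 ± 0.14 and −0.71 ± 0.14, and quantile normalization and the brightness covariate each ended the nonylphenol call. AKR1C2, an enzyme of steroid metabolism, was higher with PPT by 3.11 ± 0.14 (adjusted p = 2.42e-14). With PPT, TGF-beta and BMP genes were higher in 9 of 15 (10 adjusted over the list alone, camera adjusted p = 0.000146), with ID3 at 1.95 ± 0.29, adhesion genes in 12 of 21 with 1 lower (14 adjusted over the list alone, camera adjusted p = 1.91e-05), and DNA repair genes lower in 12 of 20 with 1 higher (15 adjusted over the list alone, camera adjusted p = 0.000302). With PPT, p53 targets were higher in 6 of 13, and cholesterol and fatty acid synthesis genes lower in 10 of 16 with 1 higher and in 5 of 8 (6, 11 and 6 adjusted over the list alone, camera adjusted p = 0.0181, 0.00375 and 0.00426), which had adjusted p = 0.0917, 0.0755 and 0.0619 with an estimated correlation. Glycolysis genes were lower in 9 of 18 with each compound and higher in 1 with PPT (9 and 11 adjusted over the list alone, camera adjusted p = 0.0109 and 0.0135, adjusted p = 0.179 and 0.182 with an estimated correlation), and these calls ended under quantile normalization. Chaperones were lower with nonylphenol in 8 of 18 (10 adjusted over the list alone, camera adjusted p = 0.00567, adjusted p = 0.276 with an estimated correlation). Ribosomal protein genes were lower in 7 and 6 of 16 (8 and 6 adjusted over the list alone, camera adjusted p = 0.00863 and 0.0122, adjusted p = 0.472 and 0.493 with an estimated correlation), with medians of −0.32 and −0.27 that were 0.13 and 0.075 under quantile normalization. Array brightness as a covariate ended both calls and that of glycolysis for nonylphenol. In total 3708 probe sets differed from estradiol with nonylphenol and 3742 with PPT, and 1751 did for nonylphenol with array brightness as a covariate.

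Across probe sets, the log2 changes of each compound were compared with those of estradiol, bearing in mind that genes are not independent replicates. Pearson's r was 0.898 for genistein 3 µM, 0.736 for genistein 10 µM, 0.759 for daidzein, 0.266 for bisphenol A, 0.523 for nonylphenol and 0.457 for PPT. Unchanged groups simulated against the same vehicle arrays gave a mean r of 0.4997, with a highest value of 0.527. The r of bisphenol A and of PPT lay under that mean, and that of nonylphenol under the highest simulated value. The order of r may partly follow a shift shared by the compounds other than genistein 3 µM, which lacked it as estradiol did. A batch of arrays cannot be told apart from the compounds here. The covariances were 0.302, 0.285, 0.294, 0.0711, 0.169 and 0.141, against a simulated 0.0232. Probe sets higher in both numbered 1223, 1177, 1197, 400, 824 and 681, against 222, 334, 340, 212, 289 and 248 for independent lists. Those lower in both numbered 1222, 1015, 1026, 341, 653 and 569, against 253, 338, 331, 168, 277 and 223. Opposite calls numbered 0, 29, 20, 256, 93 and 128, against 475, 673, 670, 380, 566 and 471 for independent lists. The 3 vehicle arrays cannot be split into parts of 2, so part of the excess may come from these shared controls.

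Some genes moved with every compound. In all 7 comparisons 247 probe sets were higher and 233 lower, among 7989 called at least once. In simulated unchanged groups with shared vehicle arrays 0 were called in all 7. Such groups give almost no calls in any comparison, with a mean of 0 shared by a pair of comparisons. That result therefore cannot show how many of the common probe sets come from the shared vehicle arrays. Part of the agreement may still come from these arrays, since 39.1% of probe sets had one sign in all 7 comparisons, against 25.0% in the simulated groups. With array brightness as a covariate 69 were higher and 67 lower in all 7, and GREB1 was no longer called for bisphenol A (adjusted p = 0.261). PRSS23 rose by 2.68 to 5.62, PGR by 2.44 to 4.45, NPY1R by 1.72 to 4.15 and GREB1 by 1.06 to 2.74. PRSS23 and PGR were dim in the vehicle arrays that all these comparisons share, at means of 4.22 and 2.87 on the log2 scale. APOD lay between −1.27 and −3.24, and FGFR4, a growth factor receptor, between −1.20 and −1.69. Averaged over the 7 compounds, PRSS23 rose by 4.29 ± 0.25 (SE, n = 3 arrays per group, limma adjusted p = 9.09e-12) and PGR by 3.62 ± 0.26, and 4638 probe sets changed, 2348 higher and 2290 lower, against 2565 with array brightness as a covariate. Any difference among the 8 groups was called for 7641 probe sets (68.8%), and for 5078 without replicate 2.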

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

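Array brightness as a covariate was chosen after seeing the data, and all other alternatives were planned. No list call and 4 gene calls were lost with the replicate number as a block, which gave 2903 probe sets for estradiol against vehicle, 4951 for genistein 10 µM and 35 for genistein 3 µM against estradiol. The numbers do not pair the samples: 6 of 24 arrays correlated best with their own number, 20 of 84 pairs were over 0.1, and the mean correlation of deviations was −0.00872 within and 0.00435 between numbers. Of 332 gene results against vehicle, 7 calls were lost under quantile normalization and 38 with the covariate, and none with log2 of signal plus 16. Of 265 in other comparisons, 14, 42 and 3 were lost. Against vehicle, 11 list calls were lost and 4 gained under quantile normalization, and 6 lost and 2 gained with the covariate. With no filter 13 were gained. Of 1399 results of list members not named in the text, 26 reversed, 21 under quantile normalization and 5 with the covariate. With no detection calls, dim genes cannot be told from background, which limits their folds. The cause was not tested for the changes that follow.

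With the covariate the counts against vehicle were 3089 for genistein 10 µM, 2349 for daidzein, 434 for bisphenol A, 1073 for nonylphenol and 2565 for the average. The others were 1460 for the genistein doses, 467 for genistein 3 µM against daidzein, and, against estradiol, 24 for genistein 3 µM, 1605 for genistein 10 µM, 833 for daidzein and 1751 for nonylphenol. The correlation of bisphenol A with estradiol was 0.281, and the estradiol median of estrogen-induced genes 0.95. Fits on 6 arrays, which have fewer samples, gave 2343 for PPT and 0 for genistein 3 µM against estradiol (limma, 1201 at an unadjusted p under 0.05 on 24 arrays). No filter gave 24 there. With an estimated correlation 35 and 28 list calls held. With log2 of signal plus 16 the bisphenol A correlation was 0.252 and the daidzein median 1.16. Under quantile normalization that correlation was 0.290. Ribosomal protein medians reversed there, to 0.037 for bisphenol A against vehicle, 0.046 for the genistein doses and −0.066 for genistein 3 µM against daidzein. Against estradiol they were 0.011 for genistein 10 µM, 0.056 for daidzein, 0.13 for nonylphenol and 0.075 for PPT.

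Leaving out 1 replicate gave 1862 (without vehicle replicate 3) to 2792 for bisphenol A, 2164 (without daidzein replicate 1) to 3143 for genistein 3 µM against daidzein, and 5078 (without replicate 2) to 6409 for any difference. Against estradiol it gave 7 (without estradiol replicate 3) to 170 (without genistein 3 µM replicate 3) for genistein 3 µM, 1537 (without genistein 10 µM replicate 2) to 2393 for genistein 10 µM, and 1429 (without daidzein replicate 1) to 2246 for daidzein. Correlations with estradiol ran from 0.684 to 0.759 for genistein 10 µM, 0.707 to 0.783 for daidzein, 0.204 to 0.357 for bisphenol A, 0.462 to 0.574 for nonylphenol and 0.411 to 0.506 for PPT. The estradiol median ran from 0.87 to 0.95.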

Other observations

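The gene families, the tests of array brightness, the score over probe sets chosen from the genistein arrays and the test of a shift shared with the genistein doses were chosen after the results were seen. Tubulin genes rose in 9 of 10 cases with estradiol and genistein 3 µM and in 7 with genistein 10 µM and daidzein, with TUBA1A at 1.24 with estradiol. Kinesin genes, motors of the spindle and of transport, rose in 11, 12, 13 and 14 of 19 cases with these compounds and fell in 2, 2, 1 and 2. With bisphenol A none rose and 4 fell, and of the tubulin genes 2 rose and 3 fell. Nonylphenol and PPT lay between, with 4 and 5 kinesin and 3 and 5 tubulin genes that rose. With nonylphenol 1 of each family fell. Histone genes fell in 12, 14, 14 and 16 of 23 cases with estradiol, genistein 3 µM, genistein 10 µM and daidzein and rose in 4 with each, with H2AC8 at −2.00, −2.67, −1.54 and −2.26. They fell in 5 cases with bisphenol A, 4 with nonylphenol and 10 with PPT, and rose in 1 with nonylphenol and with PPT. Proteasome subunit genes rose in 17 of 31 cases with estradiol and with genistein 3 µM. They rose in 16 with genistein 10 µM, 12 with daidzein, 13 with nonylphenol, 12 with PPT and 4 with bisphenol A, and fell in 2 with each of these 5. Outside bisphenol A, the medians of these families in the groups named kept their direction under quantile normalization and with the brightness covariate.

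Metallothionein genes, which bind metals, fell in 6 of 6 cases with genistein 10 µM, in 4 with daidzein, 3 with bisphenol A, 5 with nonylphenol and 5 with PPT, and in none with estradiol or genistein 3 µM. AKR1C1, an enzyme of steroid metabolism, rose by 1.17, 1.13, 1.36, 1.54 and 2.94 in the same 5 groups and stood at 0.05 and 0.22 in the other two. The metallothionein medians in these groups were −0.76, −0.55, −0.56, −0.68 and −1.07, and with the brightness covariate −0.46, −0.36, −0.21, −0.17 and −0.91, so much of the fall with bisphenol A and nonylphenol went with brightness. Under quantile normalization they kept their direction. These 5 groups also had the brighter arrays.

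Probe sets changed by bisphenol A against vehicle were also changed between the genistein doses: 1036 were higher in both (275 for independent lists), 610 were lower in both (175) and 18 were opposite (439), though these comparisons share no array, and the mean score of those shared was 0.748 in genistein 10 µM, 0.710 in daidzein, 0.785 in bisphenol A, 0.819 in nonylphenol and 0.639 in PPT, against 0.084 in estradiol and −0.062 in genistein 3 µM. That choice of probe sets partly builds in the gap between the genistein doses and the bisphenol A score relative to vehicle. The bisphenol A score relative to vehicle was 0.567 (95% interval 0.371 to 0.764) after adjustment for array brightness and 0.771 after adjustment for the ACTB ratio. Over 3480 probe sets chosen from the genistein arrays alone it was 0.488 unadjusted, then 0.337 (0.139 to 0.536) and 0.468 (0.328 to 0.607), which argues against either linear trend as the whole cause, though the brightness covariate left 434 probe sets called for bisphenol A, against 2838 without it. The log2 changes correlated at 0.673 across probe sets. Simulated unchanged groups reached 0.0315 at most, but each probe set was drawn independently there. Real arrays of the same number deviated from their group means with correlations from −0.278 to 0.321, so 0.0315 is too low a bound for real arrays. A batch of arrays and the compounds cannot be told apart, since each group may have been handled together and the labels give no batch, and a response to these treatments stays open, as untested.

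Ribosomal protein genes lay lower than in vehicle, at a median of −0.90 with daidzein. Signal-matched other probe sets had a median of −0.471 (77 probe sets), which is consistent with compression of high signals as part of the fall. Under quantile normalization the median with daidzein was −0.098, against −0.017 for the matched probe sets, so most of the fall may depend on the signal distribution. After adjustment for brightness the list median was −0.535 (95% interval −0.691 to −0.378) against −0.879 unadjusted, which argues only against a linear trend with brightness as the whole cause. A biological fall stays open, as untested.

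DNA replication genes did not rise with bisphenol A as they did with estradiol. The median gene shift between the genistein doses was −0.142, against −1.53 for bisphenol A minus estradiol, so a shift shared with that comparison accounts for little of it. For the list median of each array the difference was −1.39 unadjusted and −1.36 (95% interval −1.56 to −1.17) after adjustment for array brightness, which argues against a linear trend with brightness.

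The 6 arrays of a comparison split into 3 and 3 in 10 ways, the real one included, too few for a share under 0.05. In each comparison only 1 split, the real one, gave as many probe sets. Against vehicle, the real counts and the highest other splits were 2974 and 0 for estradiol, 3551 and 8 for genistein 3 µM, 5024 and 3 for genistein 10 µM, 5008 and 1 for daidzein, 2838 and 2 for bisphenol A, 4226 and 1 for nonylphenol, and 3518 and 15 for PPT. They were 3480 and 1 for the genistein doses and 3371 and 0 for genistein 3 µM against daidzein. Against estradiol they were 44 and 4 for genistein 3 µM, and 2581, 2437, 4114, 3708 and 3742, each with 0, for genistein 10 µM, daidzein, bisphenol A, nonylphenol and PPT. Of 100 regroupings of the 24 arrays, 1, the real one, reached 4638 for the average of treatments (highest other 567) and 7641 for any difference (highest other 2). A random assignment of arrays to groups can therefore be excluded for these counts. Arrays of a group may share a culture or a batch, so the regroupings cannot separate such causes from the compounds.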
